A study of Homo sapiens with 6 samples.

How the data were processed

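The data are 6 miRNA arrays of cultured human cell lines, 3 of Panc-1 and 3 of HPNE, grouped and numbered by the sample titles. Per the labels' protocols, RNA was extracted with a Qiagen miRNA kit and total RNA was labelled with Cy5 with Toray's 3D-Gene labelling kit, in 1 colour. The deposited scanner files hold, for each of 3200 spots, the median spot intensity in the red channel, which per the file headers was put together from 3 scans at different gains related by least squares. The values are neither background-corrected nor normalised, since blank spots lie well above 0 on every array. The deposited series table holds the authors' processed intensity values. Set against the scanner values it was rebuilt as the spot median minus the mean of the blank spots after trimming 5% at each end, times 1 factor per array that brings the median of the listed miRNAs to 25 on every array, with miRNAs left empty unless they exceeded the trimmed blank mean by 2 SD, a rule that matched the listing of all 2565 probes on each array. Its scale is thus linear, and genes were not centred. A second scanner column, labelled as a background median, correlated with the spot median across spots with r of 0.974 to 0.995 (of logs), so it was not used as a background except in an added alternative.

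The background was corrected with limma's normexp on the 320 blank spots as negative controls with an offset of 50, values were put on the log2 scale, and arrays were quantile normalised. Spots marked as unusable in any of the scans were left out, 1 miRNA spot each on HPNE 1, Panc-1 1 and Panc-1 3. A miRNA was detected where its spot exceeded the mean of the blanks by 2 SD, and the 1285 miRNAs detected on all 3 arrays of at least 1 cell line were tested with lmFit and eBayes, with Benjamini-Hochberg adjustment and a threshold of 0.05. Each miRNA had 1 probe, and a probe that names several miRNAs keeps all names. A miRNA not detected on any array of 1 cell line is given as a bound, and the number of arrays limits the precision of every value. The fold of a dim miRNA is understated by the offset. On simulated arrays with 200 miRNAs changed and 1453 tested, the test called 100% of those raised by 2 log2 units, 88.6% of those lowered by 2, 76.0% of those raised by 1 and 56.2% of those lowered by 1. The median estimates were 1.00, −0.48, 0.33 and −0.19. The test also called 53 (4.27%) of 1242 unchanged miRNAs, beside 50, 39, 38 and 27 of these changed ones. The false share of calls there thus lay well above 0.05. Where nothing was changed, it called 0 of 1450. On the arrays with 200 miRNAs changed, the miR-17~92 list was also raised by 2. That list passed, and 4 unchanged lists passed as lower after quantile normalisation and 0 after median scaling.

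The lists fixed beforehand were the miR-200 family, other epithelial, mesenchymal and fibroblast, let-7, miR-17~92 with paralogs, p53-regulated, raised and lowered in pancreatic cancer tissue, pancreatic acinar and endocrine, 14q32, 19q13, pluripotency, Xq27, HOX cluster, 9p21, miR-221 and miR-222, miR-23, miR-27 and miR-24, miR-29, miR-30, miR-15 and miR-16, miR-130 and miR-301 and miR-181 miRNAs, and those of blood, endothelial, muscle, neuronal and liver cells. They hold 304 miRNAs, of which 302 are on the array, and some miRNAs stand in several lists. Lists with at least 3 tested members were tested with camera at its preset correlation, with camera at an estimated correlation, and with fry, adjusted over the lists. The comparison, the lists, the filter and the rule for named miRNAs were chosen before the data were examined. The rule takes the 10 largest differences on each side among miRNAs detected on all arrays without overlap, the 5 largest bounds on each side, up to 4 extreme members and every called member of each list, and the 5 brightest miRNAs, from which the text names examples. Of the 207 miRNAs under the rule, 206 matched a miRNA gene by name in RefSeq's GRCh38.p14 table, which was used for names and neighbours only, since the files name no build.

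Alternatives covered the background correction, the offset of 16, the scaling (median or 75th percentile of miRNAs detected on all arrays, cyclic loess, none, spike controls), the authors' values on the log2 scale, the filter, trend and robust estimation, a log2 difference of at least 1, a replicate block and each array left out in turn. Counts per array were compared with an exact two-sided permutation test. The computation used R 4.3.3 with limma 3.58.1 and Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9.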

Results

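Human miRNA expression was measured on 6 single-colour arrays, 3 hybridised with total RNA of Panc-1 cells and 3 with total RNA of HPNE cells. Panc-1 is an established line of human pancreatic ductal adenocarcinoma, and the labels describe HPNE as normal epithelium of the pancreatic duct. Each array carried 2565 miRNA probes and 320 blank spots. A miRNA was counted as detected where its spot was brighter than the mean of the blank spots plus 2 SD. The HPNE arrays detected 887 to 1063 miRNAs (967 ± 89.0, SD, n = 3) and the Panc-1 arrays 1388 to 1474 (1436 ± 43.9, SD, n = 3). The exact two-sided permutation p was 0.1, the smallest that 3 arrays against 3 can give. Blank spots averaged 86.2 ± 8.77 intensity units on the HPNE arrays and 19.6 ± 1.58 on the Panc-1 arrays (SD, n = 3). Above 1 common floor the HPNE arrays held 849 to 991 miRNAs and the Panc-1 arrays 777 to 832. In all, 641 miRNAs were detected on all 6 arrays and 710 on none. Across miRNAs, normalised log2 values correlated with Pearson's r of 0.987 to 0.995 between HPNE arrays, 0.997 to 0.999 between Panc-1 arrays and 0.721 to 0.791 between the cell lines. The median SD of a miRNA within a cell line was 0.063 log2 units in HPNE and 0.022 in Panc-1.

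The study compared the miRNAs of the pancreatic cancer line with those of the normal duct line. Panc-1 had higher levels of the miR-17~92 cluster and its paralogs, which promote proliferation: 17 of 19 tested members passed the threshold as higher and none as lower, with a median log2 difference of 1.67 (13 higher and 5 lower with 75th percentile scaling). Epithelial miRNAs outside the miR-200 family were also higher in Panc-1, with 7 of 8 tested members (of 12 on the array) past the threshold and a median of 1.23. In contrast, miRNAs typical of mesenchymal cells and fibroblasts were lower, with 10 of 12 past the threshold as lower and a median of −1.73. When arrays were scaled to the spike controls, that median was 0.64, with 6 members higher and 5 lower. None of these 3 lists passed a test that estimates the correlation between miRNAs from the data (adjusted p = 0.274, 0.198 and 0.198). The estimated correlations were 0.316, −0.018 and −0.065, so for the last 2 lists correlated miRNAs do not explain the failure. With 3 arrays per cell line this test has few residual degrees of freedom, and no list passed it. Failing it therefore does not show that a list is unchanged. Among the strongest single differences were at least 14.9-fold higher miR-196a-5p, a miRNA of the HOX clusters that was not above background on any HPNE array, and miR-199a-3p/miR-199b-3p, lower by −3.77 ± 0.23 (log2, SE, n = 3 per cell line). The latter was detected on 2 of the 3 Panc-1 arrays and lay near background there, so its size depends on the offset. All differences are Panc-1 minus HPNE on the log2 scale after adding an offset of 50, which understates the change of dim miRNAs.

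Among miRNAs detected on all 6 arrays, miR-425-5p and miR-191-5p, which are made from 1 shared transcript, were higher in Panc-1 by 3.69 ± 0.05 and 2.60 ± 0.04 (log2, SE, n = 3 per cell line). The other differences among the 10 largest on this side were 3.60 ± 0.30 for miR-29b-3p, 3.54 ± 0.14 for miR-106b-5p, 3.35 ± 0.10 for miR-31-5p, 3.21 ± 0.12 for miR-30a-5p, 3.11 ± 0.20 for miR-19b-3p, 2.80 ± 0.08 for miR-376b-3p, 2.73 ± 0.12 for miR-30e-5p and 2.67 ± 0.11 for miR-106a-5p. On the lower side, miR-125b-5p, abundant in fibroblasts, was lower in Panc-1 by −3.42 ± 0.16 and miR-221-3p, which represses the cell cycle inhibitor p27, by −2.92 ± 0.22. The remaining 8 of the 10 largest were miR-7704 (−2.96 ± 0.30), miR-4732-5p (−2.86 ± 0.09), miR-1246 (−2.66 ± 0.22), miR-4324 (−2.57 ± 0.03), miR-6869-5p (−2.48 ± 0.09), miR-6126 (−2.43 ± 0.12), miR-204-3p (−2.41 ± 0.14) and miR-762 (−2.24 ± 0.13). Each of the 10 lower differences lay above 0 with the spike controls as the scale. The 5 brightest miRNAs over all arrays were miR-4454 at −0.40 (adjusted p = 0.085), miR-7975 at 0.40 (adjusted p = 0.085), miR-4284 at −1.18, miR-7977 at 1.30 and miR-1273g-3p at −1.41. The last 3 passed the threshold of the limma fit. After quantile normalisation miR-4454 and miR-7975 were at 15.35 or 14.75 on every array and exchanged these levels on Panc-1 2 and Panc-1 3. Their mirrored differences thus reflect an exchange of ranks, and miR-4454 was at 0.39 without normalisation between arrays. The differences of miR-4284 and miR-1273g-3p had the opposite sign without normalisation between arrays and under every other scaling except cyclic loess.

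**Figure D1:**
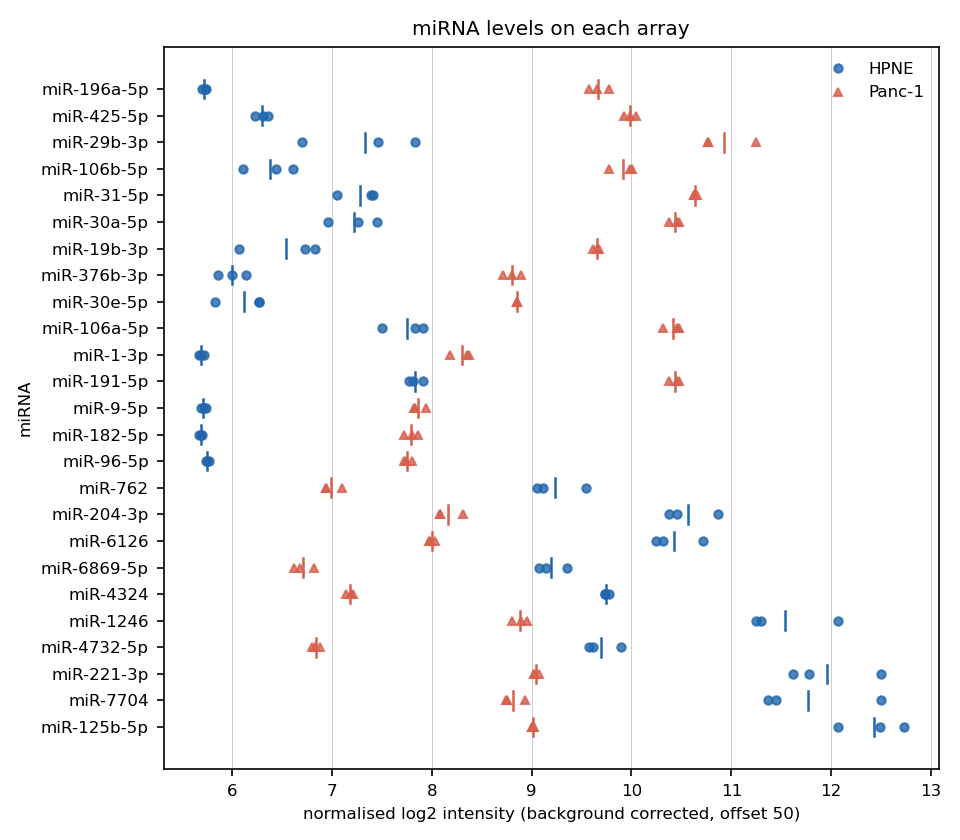
Normalised log2 intensity (x axis, background corrected, offset 50) of 25 miRNAs (y axis) on each array, with a point per array, a vertical bar at the mean of each cell line, circles for the 3 HPNE arrays and triangles for the 3 Panc-1 arrays. The points of the cell lines did not overlap for any miRNA shown, as for miR-425-5p (a log2 difference of 3.69) and miR-125b-5p (−3.42), and the 10 lower miRNAs differed by more than 0 when arrays were scaled to the spike controls.

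Several miRNAs were above background in 1 cell line only, a set that depends on each array's own floor and on the noisier blank spots of the HPNE arrays. On all 3 Panc-1 arrays and no HPNE array, 260 miRNAs were detected, and 116 of them passed the threshold, with a direction that this choice fixes. The largest bounds after miR-196a-5p were at least 5.78-fold for miR-1-3p, a muscle miRNA, at least 4.26-fold for miR-9-5p, a neuronal miRNA, and at least 4.06-fold and 3.95-fold for miR-182-5p and miR-96-5p, epithelial and sensory miRNAs of 1 cluster. In the opposite direction, 6 miRNAs were detected on all 3 HPNE arrays and no Panc-1 array, all 6 past the threshold, led by miR-708-5p at a bound of at least 1.42-fold. It was followed by miR-224-5p at 1.29-fold and miR-452-5p at 1.14-fold, which lie in 1 host gene, miR-4771 at 1.12-fold and miR-302b-3p at 1.11-fold. Each bound sets the mean of the brighter cell line against the lowest detected level of the dimmer arrays, or the miRNA's own level there where that was higher.

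The miR-17~92 members that were higher included miR-17-5p (2.35 ± 0.10), miR-20a-5p (2.57 ± 0.17), miR-93-5p (1.87 ± 0.04) and miR-92a-3p (0.90 ± 0.05). The list as a whole passed camera's test with a preset correlation (adjusted p = 2.2e-06) but not with an estimated one (adjusted p = 0.274). Members of a family can be alike in sequence, and probes that read several of them were not set apart. The counts of this list and of the families below may therefore not be of separate miRNAs. In the miR-30 family 8 of 9 tested members were higher and 1, miR-30c-1-3p at −0.21 ± 0.03, was lower. miR-30d-5p was at 2.49 ± 0.13 and the list median was 1.62 (adjusted p = 0.373 with an estimated correlation). Of the miR-15 and miR-16 family, whose members restrain the cell cycle, 9 of 11 were higher and none lower, with miR-16-5p at 2.30 ± 0.25, miR-195-5p at 1.69 ± 0.04 and a median of 0.72 (adjusted p = 0.373 with an estimated correlation). In the miR-130 and miR-301 family 5 of 6 were higher, with miR-301a-3p at 1.76 ± 0.07, miR-130a-3p at 1.51 ± 0.14 and a median of 0.92 (adjusted p = 0.376 with an estimated correlation). The miR-23, miR-27 and miR-24 clusters had 7 of 10 higher, with miR-27a-3p at 2.03 ± 0.24, miR-24-3p at 1.46 ± 0.05, miR-23b-3p at 0.41 ± 0.07 and a median of 0.52 (adjusted p = 0.198 with an estimated correlation). With 75th percentile scaling the numbers higher and lower were 7 and 2 in the miR-30 family, 5 and 3 in the miR-15 and miR-16 family (median 0.18), 4 and 1 in the miR-130 and miR-301 family and 6 and 3 in the miR-23, miR-27 and miR-24 clusters. In the miR-29 family 5 of 7 were higher and none lower, with a median of 0.33. The list did not pass camera's test (adjusted p = 0.051, and adjusted p = 0.373 with an estimated correlation) but passed as higher with median scaling (adjusted p = 0.0031), with the 75th percentile (adjusted p = 0.0013, with 3 higher and 2 lower), without normalisation between arrays (adjusted p = 0.0047) and in the authors' values (adjusted p = 0.017). With an estimated correlation it passed under none of these scalings.

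Of the imprinted 14q32 cluster, which is expressed from the maternal chromosome, 41 of 52 tested members were higher in Panc-1 and 1 was lower, or 42 and 1 adjusted over the list alone, with a median of 0.49 (adjusted p = 0.204 with an estimated correlation). The differences ranged from 2.80 for miR-376b-3p, through 2.23 ± 0.14 for miR-376c-3p and 2.11 ± 0.10 for miR-377-3p, to −0.28 ± 0.05 for miR-494-3p, which was above 0 under every other scaling except cyclic loess. The numbers higher and lower were 24 and 13 with 75th percentile scaling and 52 and 0 with the spike controls. Of the HOX cluster miRNAs, which lie among the homeobox genes of body patterning, 7 of 9 were higher, or 8 adjusted over the list alone, with miR-196b-5p at 1.69 ± 0.04, miR-10b-5p at 0.99 ± 0.07 and a median of 0.75 (adjusted p = 0.198 with an estimated correlation). With the 75th percentile 5 were higher and 4 lower. For every other list except the 19q13 cluster the numbers higher and lower were the same adjusted over the list alone.

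The mesenchymal list passed camera's test as lower (adjusted p = 0.00034), though not with an estimated correlation (adjusted p = 0.198). With the spike controls as the scale its median of 0.64 lay below the 1.75 of all tested miRNAs. The numbers higher and lower were 1 and 7 with median scaling and without normalisation between arrays and 4 and 7 in the authors' values. They were 1 and 11 with the 75th percentile and 6 and 5 with the spike controls. The lower members of the list included miR-199a-5p (−2.60 ± 0.17), miR-145-5p (−2.58 ± 0.06) and miR-143-3p (−2.01 ± 0.13), which mark smooth muscle and fibroblasts, and miR-214-3p (−1.67 ± 0.07). Of these, miR-199a-5p and miR-143-3p were detected on 2 and miR-145-5p on 1 of the 3 Panc-1 arrays, so their sizes depend on the offset. miR-100-5p was at −1.79 ± 0.05 but at 0.12 without normalisation between arrays, 0.59 in the authors' values and 2.44 with the spike controls. Also among the lower members, miR-99a-5p (−1.24 ± 0.08) and miR-22-3p (−1.18 ± 0.19) were at 0.71 and 0.76 in the authors' values. The exception of the list was miR-10b-5p, a HOX cluster miRNA, which was higher. The other epithelial list passed as higher (adjusted p = 0.0030, and adjusted p = 0.198 with an estimated correlation), led by miR-31-5p, miR-182-5p, miR-96-5p and miR-7-5p (1.93 ± 0.16). With the 75th percentile 4 of its members were higher and 2 lower. Its smallest called differences were 0.12 ± 0.04 for miR-215-5p and 0.27 ± 0.08 for miR-192-5p. The 4 of its 12 members on the array that could not be tested were miR-203a-3p, miR-205-5p, miR-205-3p and miR-375, so nothing is shown for them. Only 3 of the 9 members of the miR-200 family, the main epithelial family, could be tested, and 1 of them, miR-200b-3p at 0.12 ± 0.02, was higher, at least 1.05-fold. It did not pass with median scaling or without normalisation between arrays, and all 3 were lower with the 75th percentile. In the let-7 family, which represses RAS and HMGA2, 5 of 9 members were lower, with let-7b-5p at −1.21 ± 0.06 and let-7a-5p at −0.71 ± 0.05. The 2 higher members were let-7g-5p at 0.92 ± 0.14 and miR-98-5p at 1.40 ± 0.07. Its median was −0.51 after quantile normalisation and −0.78 after cyclic loess, but 0.80 with median scaling, 0.16 with 75th percentile scaling, 0.86 without normalisation between arrays, 0.70 with median scaling above a floor, 1.38 in the authors' values and 3.23 with the spike controls. No direction is therefore given for this family, and the list did not pass camera's test (adjusted p = 0.150).

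Among miRNAs that the literature describes as raised in pancreatic cancer tissue, 13 of 20 tested were higher in Panc-1 and 4 were lower, with a median of 0.97 (camera adjusted p = 0.013, and adjusted p = 0.425 with an estimated correlation). Those higher included miR-21-5p (2.53 ± 0.23), miR-107 (2.04 ± 0.08) and the hypoxia miRNA miR-210-3p (1.03 ± 0.10). The 4 lower were miR-221-3p, miR-222-3p (−2.11 ± 0.04), miR-181a-5p (−0.88 ± 0.03) and miR-155-5p (−0.43 ± 0.09). These directions depend on the scaling, since 20 members were higher and 0 lower with the spike controls and 1 was lower in the authors' values, where miR-181a-5p was at 0.43. Among miRNAs described as lowered in pancreatic cancer tissue, 8 of 11 tested were higher and 3 lower, the latter being miR-145-5p, miR-143-3p and miR-34a-5p (−0.56 ± 0.16). The last was at 0.53 without normalisation between arrays, 1.18 in the authors' values and 3.03 with the spike controls. The list did not pass (camera adjusted p = 0.112). The 4 miR-221 and miR-222 products had 2 lower and 1 higher, with a median of −1.09 that became 0.15 in the authors' values and 2.01 with the spike controls (camera adjusted p = 0.251). Of the miR-181 family 1 of 7 was higher and 1 lower (camera adjusted p = 0.766), against 0 and 6 with the 75th percentile, 4 and 0 without normalisation between arrays and 7 and 0 with the spike controls.

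Among the lists of other cell types, all 4 tested muscle miRNAs were higher in Panc-1, or 3 with median scaling, with cyclic loess and without normalisation between arrays and 3 with 1 lower with the 75th percentile, with miR-133b at 1.36 ± 0.05 and miR-133a-3p at least 2.27-fold higher. Of the 4, miR-206 lay near the floor in both cell lines, at 5.68 to 5.72 on the HPNE arrays and 5.75 to 5.81 on the Panc-1 arrays. All 3 tested neuronal miRNAs were higher, with miR-9-3p at 1.35 ± 0.10 and miR-128-3p at 1.25 ± 0.05. The list medians were 1.30 and 1.35 (camera adjusted p = 0.013 for both, and adjusted p = 0.198 with an estimated correlation for both). The median of each of the 11 lists called higher stayed above 0 under all the other scalings tried. With members measured in 1 cell line only placed at their bounds, no called list's median moved by more than 0.054.

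**Figure D2:**
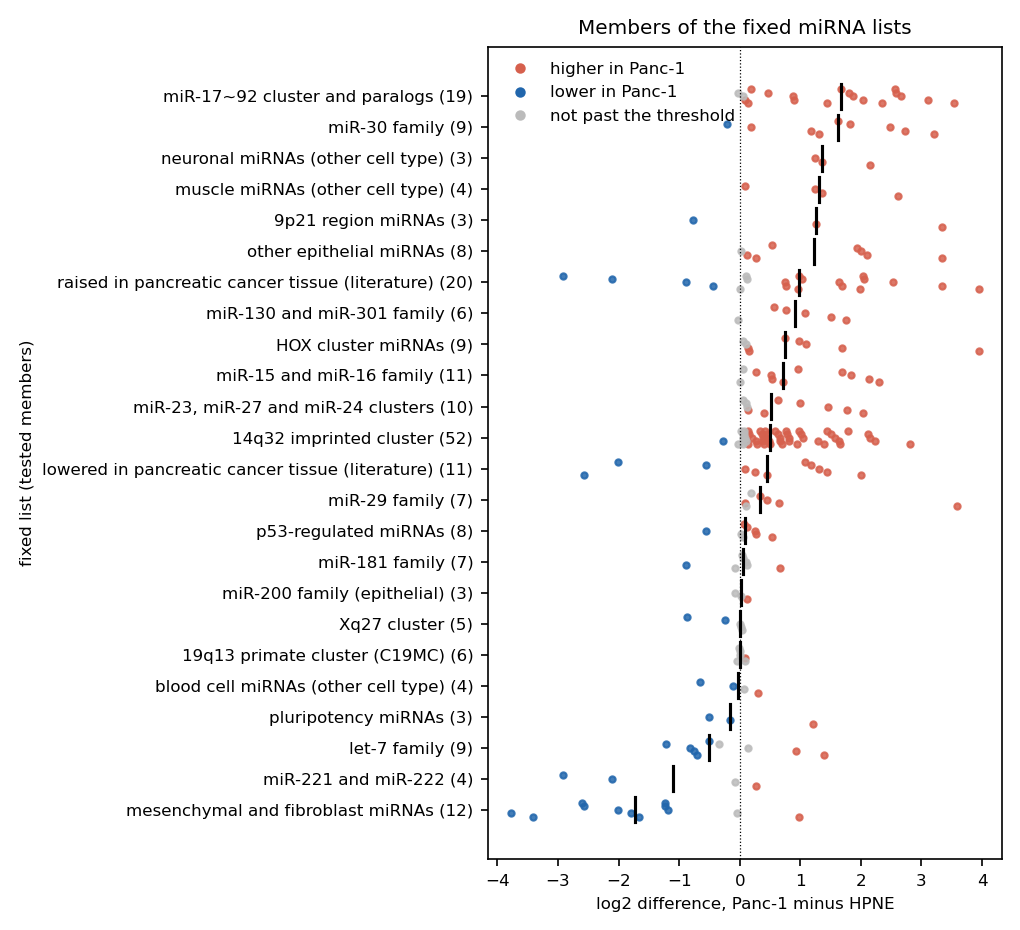
Fitted log2 differences, Panc-1 minus HPNE (x axis), of the tested members of 24 fixed lists (y axis, number of tested members in brackets), coloured by whether the member was higher, lower or not past the threshold, with a black bar at each list's median. The miR-17~92 list lay highest (median 1.67) and the mesenchymal list lowest (−1.73), but the mesenchymal median was 0.64 with the spike controls as the scale and the let-7 median ranged from −0.78 to 3.23 between scalings.

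Over all miRNAs tested, 713 of 1285 passed an adjusted p of 0.05 in the limma fit, 373 higher in Panc-1 and 340 lower, and 780 had an unadjusted p under it. Of these calls 103 higher and 93 lower reached a 2-fold difference. The values of the cell lines did not overlap for 870 tested miRNAs (67.8%). The 10% by chance for 3 arrays against 3 is no fair reference for this set, which was chosen by detection within a cell line. Among the 641 miRNAs detected on all arrays, 539 (84.1%) did not overlap and 484 passed, 169 higher and 315 lower. This excess of lower calls became an excess of higher calls without normalisation between arrays, in the authors' values and with the spike controls. The higher share of calls was 52.3% after quantile normalisation, 73.2% without normalisation between arrays (377 higher and 138 lower), 67.3% in the authors' values (406 and 197), 13.7% with 75th percentile scaling (164 and 1031) and 98.9% with the spike controls (1179 and 13). These scalings moved the median difference of all tested miRNAs from 0.02 to −0.68 with the 75th percentile, 0.30 in the authors' values and 1.75 with the spike controls, so each difference is relative to a scale. The scalings without spike controls, the authors' values included, kept 126 of the higher and 113 of the lower calls. With the spike controls in addition they kept 126 and 10, of which 5 belong to the mesenchymal list. Of the 28 lists, 24 had at least 3 tested members, and 12 of these passed camera's test with the preset correlation, 11 as higher and 1 as lower. Camera sets a list against all other tested miRNAs, and nearly all list members have a name number under 1000. Such miRNAs were higher as a class (medians of 0.25 against −0.21 for later numbers, among miRNAs detected on all arrays). A general rise of low-numbered miRNAs was not separated from the lists called higher. Of the 24, 0 passed with an estimated correlation (6 had an unadjusted p under 0.05) and 20 passed fry, which tests whether a list's miRNAs move one way on balance.

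**Figure D3:**
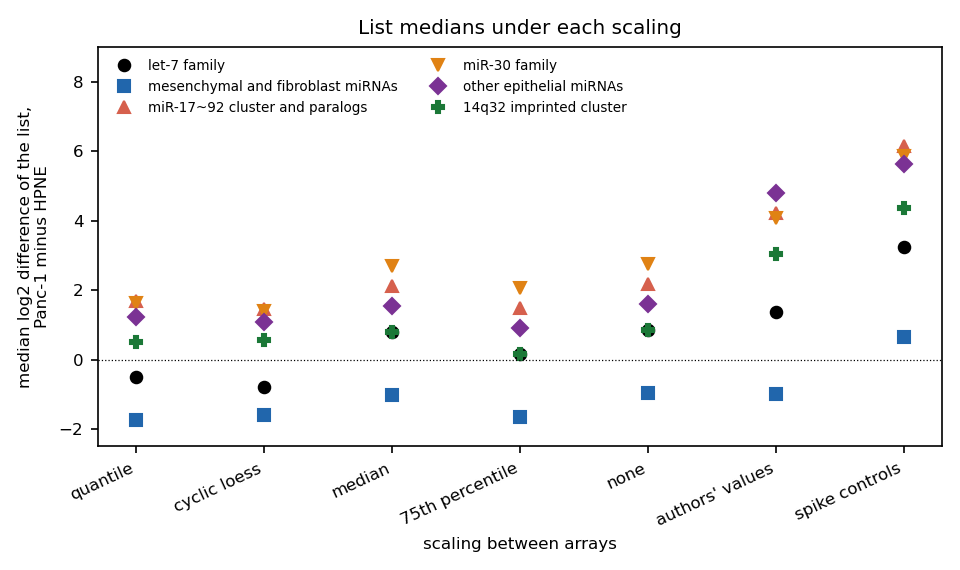
Median log2 difference, Panc-1 minus HPNE (y axis), of the members of 6 fixed lists under each scaling between arrays (x axis), with a symbol per list. The miR-17~92, miR-30, other epithelial and 14q32 lists lay above 0 under all 7 scalings shown, the mesenchymal list lay below 0 except with the spike controls (0.64), and the let-7 list lay below 0 only after quantile normalisation (−0.51) and cyclic loess (−0.78).

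The 3 HPNE arrays lay on 1 slide and the 3 Panc-1 arrays on another, so slide and cell line cannot be told apart. Nothing in the labels says that the replicates were separate cultures, so p-values measure only the spread between these arrays, which may be technical.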

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

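In this part the test of a single gain per array was chosen only after the result was seen. Control probes that the comparison of miRNAs does not use carried signal on all 3 Panc-1 arrays above the level on all 3 HPNE arrays, in mean intensity after subtracting the blank spots, although blank spots and spike controls were brighter on HPNE. The values on Panc-1 were 7792 for S-Probe1014 (3860 on HPNE), 1630 for S-Probe1008 (115 on HPNE), 1174 for S-Probe1013 (304 on HPNE), 973 for S-Probe1018 (118 on HPNE), 934 for S-Probe1002 (125 on HPNE) and 544 for S-Probe1009 (24.4 on HPNE). They were 227 for S-Probe1016 (41.8 on HPNE), 157 for S-Probe1011 (6.39 on HPNE), 97.2 for S-Probe1006 (14.02 on HPNE), 84.7 for S-Probe1007 (27.3 on HPNE) and 74.4 for S-Probe1010 (4.42 on HPNE). They were 16.3 for S-Probe1012 (8.11 on HPNE), 15.5 for S-Probe1005 (9.04 on HPNE), 5.57 for S-Probe21 (3.88 on HPNE) and 2.77 for Negative Control 1 (1.52 on HPNE). What the S-Probes measure is not given in the sources used here. In the opposite direction, the median spike control was 5.15 times as bright on HPNE (21738) as on Panc-1 (4224), and S-Probe28 averaged 10983 on HPNE and 1373 on Panc-1.

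The Panc-1 arrays detected 469 more miRNAs than the HPNE arrays on average, and their summed miRNA signal was 2.69 times as large. A single scanner gain per array is argued against, since the spike signal per 1000 units of summed miRNA signal was at least 8.93 times as large on every HPNE array as on any Panc-1 array. Noisier blank spots could account for the number detected, since the blank SD was 2.51 on HPNE and 0.875 on Panc-1 and each array sets its own floor. With arrays scaled to the median of the miRNAs detected on all 6 and the highest floor used for all, the numbers did not merely overlap, as foreseen, but turned, and the lowest Panc-1 array minus the highest HPNE array gave −214. At which step the spike controls were added is not given in the sources used here, so a difference in labelling or in labelled RNA stays open, as do the slide and the cell lines themselves, which were not tested.

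The 10 splits of the 6 arrays into 3 and 3 are too few to give a share under 0.05. The split by cell line gave 713 miRNAs past the threshold and the highest other split 0 in limma (with at most 6 at an unadjusted p under 0.05), so 1 of the 10 splits, the real one, gave as many. It gave 12 lists, and the highest other split gave 10, so again 1 of the 10 gave as many. Every other split puts arrays of both cell lines in each group. The difference between the lines thus enters both its contrast and its spread, so its 0 miRNAs and up to 10 lists are no reference for chance.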

How the results depend on the processing

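Of these settings, normexp without the blank spots, normexp after subtracting the local background column, median scaling above a floor and spike control scaling above a floor were chosen only after the data had been seen. The number of calls lay between 477 and 782 under no background correction, the floor after quantile normalisation, offset 16, median scaling, cyclic loess, no normalisation between arrays, the authors' values, no filter, detection on all 6 arrays, trend and robust estimation, normexp without the blank spots and median scaling above a floor, against 713. It lay between 593 and 751 with each array left out in turn (304 to 375 higher and 285 to 377 lower), where 12 to 13 lists passed, 11 to 12 as higher and 1 as lower, and the difference in detected miRNAs was 428.5 to 516.5. The replicate numbers did not pair the arrays, since same-numbered arrays deviated from their group means with r of −0.21, 0.11 and −0.20 and not every array correlated best with its own number, and a fit with the number as a replicate block gave 629 calls, 320 higher and 309 lower. The count moved to 1195 with 75th percentile scaling (164 higher, 1031 lower), 1192 with the spike controls (1179 higher, 13 lower), 196 at a log2 difference of at least 1 (103 higher, 93 lower, fewer by construction) and 7 after subtracting the local background column (4 higher, 3 lower), whose values followed the spots themselves. Lower calls numbered 138 without normalisation between arrays and 197 in the authors' values, where 948 miRNAs were tested, and 167 were higher among miRNAs detected on all arrays, where 641 were tested. Of the 713 calls, those called the other way numbered 15 without normalisation, 20 with median scaling above a floor, 21 with median scaling, 40 in the authors' values, 162 with the 75th percentile and 287 with the spike controls. Dim miRNAs lie near 50 before scaling, so a factor per array moves them all, which the 75th percentile median of −0.68 against 0.02 without normalisation shows. On the arrays simulated with 200 miRNAs changed and the miR-17~92 list raised, quantile normalisation pushed 48 bright unchanged miRNAs to a median of −0.38. It put the unchanged let-7 list at −0.35 there, against 0.0007 with median scaling. Quantile normalisation could thus lower bright miRNAs on the deposited arrays, where let-7a-5p became 0.80 with median scaling. The other causes were not tested. Signal over background limits the HPNE arrays most, whose blank SD was 2.51 against 0.875, and at 3 SD above the blanks Panc-1 detected 558 more miRNAs than HPNE, against 469.

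Lists past the threshold numbered 6, all higher and 0 lower, after local background subtraction, 4 with the spike controls (3 higher), and 11 to 15 elsewhere, with 2 lower after cyclic loess, the second being let-7, and 0 lower among miRNAs detected on all arrays, where the mesenchymal list had fewer members and an adjusted p of 0.092. In the authors' values 7 lists had fewer than 3 members with a value on all 6 arrays and so no test. The miR-17~92, 14q32 and raised in pancreatic cancer lists passed camera's test with the preset correlation under every setting, and 0 lists passed with an estimated correlation under any. With the spike controls the other epithelial, HOX, miR-23, miR-27 and miR-24, miR-30, miR-15 and miR-16, miR-130 and miR-301, muscle and neuronal lists no longer passed, and in the authors' values the miR-130 and miR-301 list did not.

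List directions reversed as follows, with camera's adjusted p. For let-7 it was 0.000581 with median scaling, 0.00579 with the 75th percentile, 0.00572 without normalisation, 0.0280 in the authors' values, 0.0280 with median scaling above a floor, 0.250 with the spike controls and 0.566 after local background subtraction (0.000581 to 0.604 over all settings). For the 19q13 cluster it was 0.431 with median scaling, 0.552 with the 75th percentile, 0.476 without normalisation, 0.334 without a filter, 0.856 with median scaling above a floor, 0.0785 with the spike controls, and 0.955 and 0.999 without HPNE 1 and HPNE 2 (0.582 to 0.999 with each array left out) (0.0785 to 0.999). For the miR-200 family it was 0.703 with median scaling, 0.701 with the 75th percentile, 0.818 without normalisation and 0.613 with the spike controls (0.613 to 0.982). With the spike controls it was 0.183 for the list lowered in pancreatic cancer (0.0152 to 0.317) and 0.808 for miR-221 and miR-222 (0.190 to 0.808). With the 75th percentile it was 0.772 for pluripotency miRNAs (0.184 to 0.886) and 0.904 for miR-181 (0.206 to 0.906). Without a filter it was 0.982 for blood cell miRNAs (0.0649 to 0.982). After local background subtraction it was 0.961 for the mesenchymal list (1.4e-14 to 0.961), 0.432 for pluripotency miRNAs, 0.632 for Xq27 (0.131 to 0.651), 0.273 for miR-221 and miR-222 and 0.632 for blood cell miRNAs.

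Among 84 miRNAs followed through the settings, single ones reversed as follows, in log2 differences. With the spike controls they were 0.22 for miR-4732-5p, 0.38 for miR-6869-5p, 0.75 for miR-4324, 0.91 for miR-491-5p, 1.01 for miR-762, 1.05 for miR-125b-5p, 1.05 for miR-204-3p, 1.07 for miR-6126, 1.08 for miR-7704, 1.18 for miR-30c-1-3p, 1.23 for miR-513a-5p, 1.25 for miR-371a-5p, 1.28 for miR-221-3p, 1.30 for miR-1246, 1.44 for miR-222-3p, 1.70 for miR-155-5p, 2.29 for miR-181a-5p, 2.44 for miR-100-5p, 2.58 for let-7b-5p, 2.71 for miR-4454, 3.03 for miR-34a-5p, 3.20 for let-7a-5p, 3.27 for miR-1273g-3p, 3.56 for miR-4284 and 3.59 for miR-494-3p. With median scaling they were 0.0585 for miR-100-5p, 0.19 for let-7b-5p, 0.33 for miR-4454, 0.47 for miR-34a-5p, 0.80 for let-7a-5p, 0.88 for miR-1273g-3p, 1.06 for miR-494-3p and 1.17 for miR-4284. With median scaling above a floor they were 0.0487 for let-7b-5p, 0.17 for miR-4454, 0.50 for miR-34a-5p, 0.67 for let-7a-5p, 0.74 for miR-1273g-3p, 1.03 for miR-4284 and 1.06 for miR-494-3p. Without normalisation they were 0.12 for miR-100-5p, 0.25 for let-7b-5p, 0.39 for miR-4454, 0.53 for miR-34a-5p, 0.86 for let-7a-5p, 0.94 for miR-1273g-3p, 1.13 for miR-494-3p and 1.24 for miR-4284. In the authors' values they were 0.43 for miR-181a-5p, 0.59 for miR-100-5p, 0.72 for let-7b-5p, 0.85 for miR-4454, 1.18 for miR-34a-5p, 1.34 for let-7a-5p, 1.42 for miR-1273g-3p, 1.70 for miR-4284 and 1.74 for miR-494-3p. With the 75th percentile they were −0.58 for miR-200b-3p, 0.16 for let-7a-5p, 0.25 for miR-1273g-3p, 0.43 for miR-494-3p and 0.54 for miR-4284. With cyclic loess miR-7975 became −1.52. After local background subtraction they were −0.41 for miR-23b-3p, −0.31 for miR-7975, −0.0878 for miR-377-3p, 0.0024 for miR-30c-1-3p, 0.0194 for miR-224-5p, 0.0454 for miR-451a, 0.0591 for miR-513a-5p, 0.12 for miR-199a-5p, 0.14 for miR-204-3p, 0.16 for miR-34a-5p, 0.19 for miR-222-3p, 0.20 for miR-181a-5p, 0.25 for miR-199a-3p/miR-199b-3p, 0.82 for miR-1246, 0.82 for miR-100-5p, 1.26 for let-7a-5p and 2.20 for miR-4454. In the other comparisons of these 84 miRNAs with a setting, the direction and the side of the threshold were kept in 1688, the call was lost in 119 and gained in 10. Reversals of miRNAs not followed are not listed, such as let-7c-5p (−0.82, but 1.25 in the authors' values) and let-7d-5p (−0.51, but 1.38).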

Other observations

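In this part the tests of a lower miRNA content, of quantile normalisation and of RNA of neurons were chosen only after the result was seen, and so were the readings of the tests of muscle RNA and of a general rise given below. In the 9p21 region, which holds CDKN2A and is often lost in pancreatic cancer, miR-31-3p was higher in Panc-1 by 1.26 ± 0.04 (log2, SE, n = 3 per cell line) together with miR-31-5p, whereas miR-491-5p was lower by −0.77 ± 0.04, or higher by 0.91 with the spike controls as the scale (camera adjusted p = 0.415 for the list). Of the p53-regulated miRNAs 5 of 8 tested were higher, with miR-194-5p at 0.53 ± 0.03, and 1 was lower, miR-34a-5p, which became 0.47 with median scaling (camera adjusted p = 0.251). These counts depend on the scaling, with 0 higher and 5 lower with the 75th percentile and 8 and 0 with the spike controls. Among pluripotency miRNAs 3 of 11 could be tested, and miR-373-5p was higher by 1.21 ± 0.07 while miR-371a-5p, of the same cluster, was lower by −0.51 ± 0.07, or higher by 1.25 with the spike controls, and miR-302b-3p was lower (camera adjusted p = 0.766). Of the Xq27 cluster 5 of 19 were tested and 2 were lower, with miR-513a-5p at −0.87 ± 0.06, or 1.23 with the spike controls (camera adjusted p = 0.502).

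Of the primate 19q13 cluster, expressed mainly in placenta, 6 of 36 members were tested and 1 was higher, or 0 adjusted over the list alone (camera adjusted p = 0.766). The numbers higher and lower were 0 and 6 with the 75th percentile and 5 and 0 with the spike controls. Pancreatic acinar miRNAs had 1 of 7 tested, which was not detected on any HPNE array. It passed at a fitted difference of only 0.09, for which no fold can be given as a bound. It did not pass with median scaling or without normalisation between arrays. Endocrine miRNAs had 1 of 4 tested, miR-7-5p, which was higher. Both endothelial miRNAs were higher, with miR-126-3p at least 2.59-fold, but with 75th percentile scaling 1 was higher and 1 lower. Among 4 tested blood cell miRNAs 1 was higher and 2 were lower, with the red cell miRNA miR-451a at −0.66 ± 0.08 (camera adjusted p = 0.805), and 0 of 2 liver miRNAs could be tested.

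Among the 641 miRNAs detected on all arrays, the 231 with a name number under 1000, which were named earlier, had a median difference of 0.25 (125 higher, 62 lower) and the 410 with a higher number −0.21 (44 higher, 253 lower). In the authors' values the counts were 177 higher and 26 lower against 129 and 115, with a high-numbered median of 0.05. With the spike controls they were 222 and 2 against 389 and 2. The direction of the high-numbered class thus depends on the scaling, but the gap between the classes remains. Quantile normalisation alone does not account for this gap, since the gap between the medians was at least 0.80 without it or loess and 2.10 in the authors' values. Brightness alone does not either, since within 5 classes of mean level the gap averaged 0.788 (permutation p = 1e-04, the smallest that 10000 permutations can give), although it grew from 0.023 in the dimmest class to 1.83 in the brightest. Less miRNA in the labelled RNA of all HPNE arrays, with other RNA read by the high-numbered probes, could give such a gap, since relative to the spike controls the low-numbered miRNAs were higher by 3.96 and the high-numbered ones by 1.83. As all HPNE arrays share a cell line and a slide, this and a difference between the cell lines cannot be told apart.

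The 7 tested muscle and neuronal miRNAs were all higher in Panc-1, with a median of 1.35, and none stands in another of the lists. For RNA of neurons, miR-124-3p was detected on 0 Panc-1 arrays. This 1 probe lay near the floor in both cell lines (5.71 on HPNE and 5.69 on Panc-1). No array thus shows that it reads its miRNA, and it cannot decide. A general rise of low-numbered miRNAs stays open, since the members were taken up because their lists had passed as higher, so that the percentile of their median among random sets of such miRNAs of like HPNE level, 99.96, excludes nothing. For RNA of muscle, the bound set beforehand, at least 2 of miR-499a-5p, miR-208a-3p and miR-208b-3p detected on no Panc-1 array, was met by 2, but it was set aside after the result was seen: miR-208a-3p and miR-208b-3p are miRNAs of heart and slow muscle, which other muscle need not hold, and miR-499a-5p lay near the floor in both cell lines (5.73 on HPNE and 5.82 on Panc-1) and decides nothing. RNA of muscle or of neurons, a general rise and expression by Panc-1, which may be the source as a hypothesis, therefore cannot be told apart.

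miRNA genes of a shared transcript may differ between the cell lines together. Among 137 pairs of neighbouring miRNA genes within 10 kb in RefSeq's GRCh38.p14 annotation, the mean absolute difference between the log2 differences of neighbours was 0.519, against 0.647 in random pairs (permutation p = 0.016), and 83.2% of pairs had the same sign. The value was 0.509 for the 97 pairs without a member of the fixed 14q32 list (permutation p = 0.024). These still hold the pairs of MIR1185-1 with MIR300 and with MIR1185-2, which lie in that cluster. For all 137 pairs, random pairs shuffled within the name number classes gave 0.722 (permutation p = 2e-04). The values go with the hypothesis, but clustered miRNAs can be alike in sequence and probes that read their neighbours as well were not set apart, and genes are not independent replicates.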
